A study of Mus musculus with 8 samples.

How the data were processed

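Polyadenylated RNA was measured in whole mouse embryos (B6CBA F1 crosses) that had been injected at the 1-cell stage with mRNA for mCherry (the control, a fluorescent protein), for Snrpb, for Snrpd2, or for Snrpb and Snrpd2 together. Per the labels' protocols, RNA was extracted 5 h after injection (1-cell stage) or 24 h after injection (2-cell stage) with the Qiagen RNeasy Micro kit, libraries were made with the SMARTer Stranded RNA-Seq kit, and sequencing was done on a HiSeq2500. The 4 injections and 2 stages gave 8 conditions with 1 library each, and each library was a pool of 40 embryos from 3 independent experiments. The pool hides the spread between embryos and between experiments, so no condition had a replicate.

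Each library came as 1 deposited table of 22667 Ensembl gene identifiers, of which 1114 had no value in any library and 21553 were used. The deposited counts were whole numbers of reads per gene. The second deposited value was cRPKM, an RPKM value (reads per kilobase scaled to the library total). For 2662 genes with more than 2000 reads it equalled the deposited count divided by a fixed length per gene and by the library total, with a deviation of at most 0.17%. The genome build was mm9, per the submitters' processing notes. The aligner, the gene annotation, the treatment of reads that map to several genes and the use of strand are not given in the sources used here. Genes with near-identical copies (such as members of the Tdpoz, Obox and Gm families named in the report) are therefore uncertain, and so are genes that overlap others. Gene symbols were taken from the GENCODE vM21 annotation of GRCm38 by Ensembl identifier, and 20759 of the listed identifiers had one (20451 of those with a value). Because that build is not mm9, no coordinates were taken from it. Gene totals carry no exon junctions, so splicing was not analysed here.

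Depth ranged from 39492734 to 59979046 counted reads per library. A count of 0 allows up to 3 reads, which was between 0.05 and 0.076 CPM in these libraries. Intervals on the ratio of 2 libraries were exact conditional binomial intervals at 95% confidence. They and the floor cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Folds against a library with 0 reads were computed against a floor of 3 reads in that library, and stage folds, which pool the reads of the 4 libraries of a stage, against a floor of 3 reads over the stage. Both are given as bounds set by the floor alone. They leave out the counting error of the other library, so the lower limit of the interval can lie below them. For Ctsk in the 1-cell Snrpb library that limit was 355-fold against a floor value of 437-fold. The median of a list of genes is given with an order-statistic interval over its members.

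Differential expression was tested on the counts as deposited with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment) in R 4.3.3. The first model had terms for injection and stage and was fitted to all 8 libraries, so that the 4 injections stood in for replicates of the stage effect and the 2 stages for replicates of each injection. It had 3 residual degrees of freedom, 16264 genes and a common dispersion of 0.043. The second model had 4 groups, stage by injected (3 libraries) or control (1 library), with 4 residual degrees of freedom, 16867 genes and a common dispersion of 0.0362. It gave the effect of any Snrp injection at each stage and the difference between the 2 effects (stage dependence), and the lone control was assumed to vary like the injected libraries. P-values from these models measure the spread between differently injected libraries or between stages, not between replicate pools. Calls were made at an adjusted p of 0.05.

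Libraries were also compared 1 against 1 with TMM scaling, for genes with at least 50 reads in either library, and genes were counted when the whole interval lay beyond no change and the ratio was at least 2-fold. These ratios have no replicate check and describe the libraries, not the conditions. List medians in such ratios used a prior of 0.5 reads and were ranked among 10000 random lists of the same size matched on mean expression in 20 bins. For ratios that share the mCherry control, 50 simulated sets of unchanged libraries gave the correlation and the number of shared genes expected from the shared control at the fitted dispersion. The progress of each injection through the stage change was the slope, across genes, of its own change from the 1-cell to the 2-cell stage on the mean change of the other injections, with a standard error from 200 bootstraps over genes.

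The 23 gene lists held 796 genes, of which 758 were found. They were the Sm core proteins (which include the injected genes), snRNP-specific and LSm proteins, snRNP assembly, SR proteins, hnRNP proteins, nonsense-mediated decay, DNA damage signalling, homologous recombination and Fanconi anaemia, end joining with excision and mismatch repair, p53 targets, apoptosis, 2-cell-stage genes, zygotic housekeeping activation genes, ribosomal proteins, proteasome, oocyte and maternal-effect genes, cell cycle regulators, interferon and RNA-sensing genes, the unfolded protein and integrated stress response, cumulus and granulosa cell markers, sperm and spermatid markers, later-embryo lineage markers, and blood, fibroblast and oviduct markers. Ercc5 is in the excision repair and p53 lists, Sesn2 in the p53 and stress response lists, and Bax in the p53 and apoptosis lists. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with a correlation estimated from the data. Per-gene counts for lists were taken over all genes and, where stated, adjusted over the list alone.

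The lists, models, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule named Snrpb and Snrpd2 always, then the 10 genes with the largest rise and the 10 with the largest fall in each tested model among those past the threshold and changed the same way in every pair of libraries. For the combined injection against mCherry at each stage it took the 10 higher and 10 lower genes ranked by the interval bound nearest to no change and moved the same way in both single injections. For each single injection it took the first 3 genes each way, and from each list described the 2 to 4 members with the highest mean expression. Results for some genes that the rule selects are not reported here. Genes named outside that rule are said to have been chosen after their values were seen.

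The alternatives were DESeq2 1.42.0 size factors (RLE), library totals alone, no expression filter, a filter of 50 reads in 2 libraries, the DESeq2 Wald test, limma on log2(cRPKM + 0.1) and on log2(cRPKM + 1), Snrpb and Snrpd2 left out, no injection term, each library left out in turn, 20 or 200 reads and 1.5-fold or 3-fold for the ratios, ratios of cRPKM, and the estimated correlation for lists. 3 further alternatives were added after the data were seen. They left out Ccdc82 (the gene with the most reads in every library), took Snrpb and Snrpd2 out of the Sm core list, and used genes with 200 reads in all 4 1-cell libraries for 1 correlation.

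The steps were tested on simulated data in which 200 genes were changed. For the stage effect (15898 genes), 54.2% of genes changed 2-fold and 76.8% of those changed 4-fold were recovered, and 6 unchanged genes were called. For any injection at the 2-cell stage (16596 genes) the shares were 40% and 76% with 12 unchanged genes called, and at the 1-cell stage (16575 genes) 34.3% and 69% with 7. In this last simulation camera also called 1 list, against 0 in the other two, although no list had been changed as such. For the ratio of the 2-cell combined to mCherry libraries (12900 genes), all changed genes were recovered at 2.83-fold and 4-fold, 3 unchanged genes were counted, and the intervals held the true ratio for 95.2% of genes. This last simulation drew reads with counting error alone, which is the error the intervals assume. It therefore checks the computation and not how the intervals fare with spread between pools. Tables were handled in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1) and figures drawn with matplotlib 3.10.9.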

Results

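The data were 8 transcriptomes of mouse embryos around the activation of the embryonic genome, 4 from the 1-cell stage (zygotes, 5 h after injection) and 4 from the 2-cell stage (24 h after injection). At each stage, 1 library came from embryos given mCherry mRNA, 1 from embryos given Snrpb mRNA, 1 from embryos given Snrpd2 mRNA and 1 from embryos given both. Snrpb and Snrpd2 encode Sm proteins, which form the ring around the small nuclear RNAs of the spliceosome. The series asks how raising these proteins in the early embryo bears on splicing and the DNA damage response when the embryonic genome becomes active. Library totals at the 1-cell stage were 55774642 (mCherry), 59979046 (Snrpb), 54149817 (Snrpd2) and 49461122 (both) reads, and at the 2-cell stage 42536501, 40558073, 44648717 and 39492734 reads. Between 13631 and 13860 genes had at least 10 reads in the 1-cell libraries and between 15541 and 15810 in the 2-cell libraries. The gene with the most reads, Ccdc82, took 10.76% of reads in the 1-cell mCherry library, 7.24%, 6.09% and 7.44% in the other 1-cell libraries, and 12.74% to 13.62% at the 2-cell stage. No pair of libraries was identical. The closest pair, 1-cell Snrpd2 and 1-cell Snrpb with Snrpd2, had r = 0.9878 across genes, and 2.56% of genes had equal read numbers.

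The injected mRNAs were measured first, as a check of the labels. Snrpb (ENSMUSG00000027404) reached 43849.91 cRPKM in the 1-cell library given Snrpb and 11913.49 cRPKM in the one given both, against 7.96 cRPKM with mCherry and 6.09 cRPKM with Snrpd2. Its ratio to mCherry was 5870-fold (95% interval 5380 to 6430) for Snrpb alone and 1470-fold (1340 to 1610) for both. Snrpd2 (ENSMUSG00000040824) stood at 17926.25 cRPKM with Snrpd2 alone and 9141.58 cRPKM with both, 9720-fold (6680 to 14700) and 4740-fold (3260 to 7200) above the 1.89 cRPKM with mCherry. At the 2-cell stage the ratios to mCherry were 97.1-fold (90.7 to 104) and 49.2-fold (45.9 to 52.8) for Snrpb, and 469-fold (391 to 568) and 437-fold (364 to 530) for Snrpd2. Every library whose label names Snrpb or Snrpd2 therefore held that mRNA in large excess.

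The excess of Snrpb shrank more between the stages than that of Snrpd2. Snrpb reads were 31.9-fold lower (31.6 to 32.1) at the 2-cell than at the 1-cell stage after Snrpb alone and 15.7-fold lower (15.5 to 15.9) after both, while Snrpd2 reads were 4.27-fold (4.23 to 4.31) and 2.23-fold (2.21 to 2.26) lower. With cRPKM these falls were 25.7-fold and 13.6-fold for Snrpb, and 3.42-fold and 1.93-fold for Snrpd2. The folds thus depend on the scaling between stages, which the intervals do not cover. The combined injection gave 4.0-fold less Snrpb than Snrpb alone at the 1-cell stage and 1.97-fold less at the 2-cell stage, and 2.05-fold and 1.07-fold less Snrpd2 than Snrpd2 alone. In embryos that received neither mRNA the genes' own transcripts were higher at the 2-cell stage, 1.9-fold for Snrpb and 4.85-fold for Snrpd2 with mCherry. Snrpd2 reads in the Snrpb libraries were 0.478 times (0.226 to 0.958, 13 against 27 reads) the mCherry value at the 1-cell stage and 0.488 times (0.347 to 0.68, 54 against 115 reads) at the 2-cell stage. Snrpb reads in the Snrpd2 libraries were 0.784 times (0.683 to 0.899) and 1.42 times (1.3 to 1.55) the mCherry value. These are ratios of single pooled libraries and have no replicate check.

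**Figure D1:**
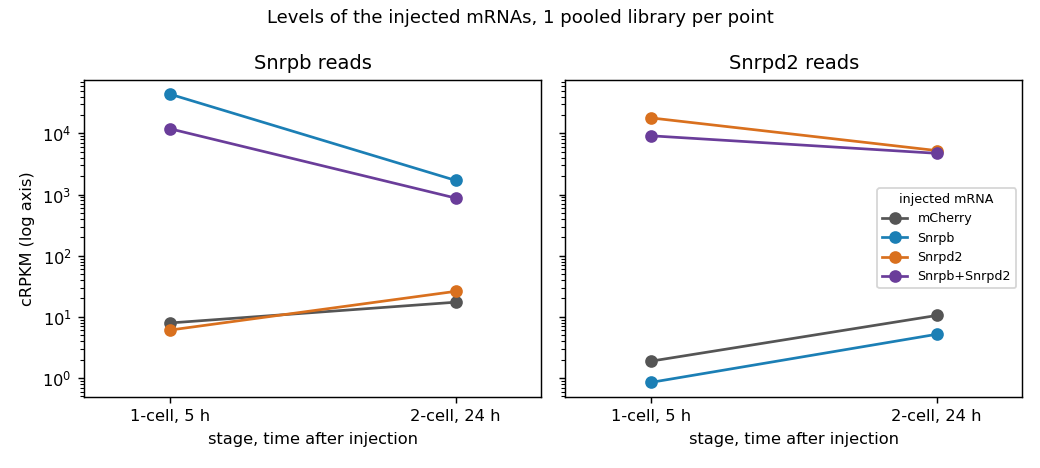
Level of Snrpb (left) and Snrpd2 (right) in cRPKM on a log axis against stage, with 1 point for each of the 8 pooled libraries and lines joining libraries of the same injection. The libraries given an mRNA lie far above the others at both stages, for Snrpb at 43849.91 and 11913.49 cRPKM (1-cell) against 7.96 with mCherry.

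The passage from the 1-cell to the 2-cell stage, over the 4 injections, was the comparison with the most changed genes. Genes with next to no reads at the 1-cell stage appeared at the 2-cell stage. Tdpoz4, of a family of POZ-domain genes, was 8610-fold higher (1550 to 340000, 7876 against 1 read, log2 12.47, SE 0.33, adjusted p = 1.25e-08). Sox11, a transcription factor gene of the HMG-box class, was at least 893-fold higher and reached 7.48 ± 1.52 cRPKM (SD, n = 4), and 1700013H16Rik was at least 981-fold higher. Other genes among the 10 largest rises were Gm6055 (at least 588-fold), Gabra4 (at least 433-fold, a GABA receptor subunit), the transcription factor genes Klf14 (at least 302-fold) and Foxf2 (at least 284-fold), Ggt6 (at least 280-fold), Ciita (at least 276-fold, the class II transactivator) and Gm5773 (at least 267-fold), with edgeR adjusted p between 3.73e-07 and 6.45e-06. Tdpoz4, Gm6055 and Gm5773 have close copies in the genome and are uncertain.

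The 10 largest falls included transcripts that were abundant in the 1-cell libraries. Txnip, which encodes the thioredoxin-interacting protein, fell 29.1-fold from 389 ± 25.3 to 16.0 ± 1.55 cRPKM (SD, n = 4, log2 −4.87, SE 0.12, adjusted p = 1.23e-08). Nup93, a nuclear pore gene, fell 25.4-fold from 207 ± 10.1 to 9.76 ± 1.1 cRPKM, and Bub1b, the spindle checkpoint kinase BubR1, fell 31.5-fold from 130 ± 15.0 to 4.98 ± 0.306 cRPKM. Ercc5, the XPG nuclease of excision repair, fell 29.9-fold from 12.3 ± 1.18 to 0.482 ± 0.162 cRPKM (SE 0.24, adjusted p = 6.12e-08). Akr1c18, which encodes a progesterone-degrading enzyme, fell 36.5-fold from 19 ± 8.8 to 0.603 ± 0.839 cRPKM (adjusted p = 1.98e-05). The others of the 10 were Stk32c (26.3-fold), Vwa5a (24.2-fold), Nlrp10 (19.3-fold), Gykl1 (11.5-fold) and Col5a2, which was at least 21-fold lower (0 against 69 reads, adjusted p = 0.00258) but did not pass with limma on cRPKM values.

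Of 16264 genes tested, 6198 rose and 5198 fell (edgeR, adjusted p under 0.05), and 5984 and 5095 of them moved the same way in all 4 injections. Changes of at least 2-fold numbered 4776 up and 3211 down, and changes of at least 8-fold 2451 up and 255 down. Without the 1-cell mCherry library, which stood apart from the other 1-cell libraries as described for the injections, 5753 rose and 5117 fell, 5568 and 4928 of them among the genes called with it. Scaling set the balance of up and down, since the median of all genes was 0.154 (log2) with TMM and 0.413 with library totals, which called 7273 higher and 4161 lower, while limma on log2(cRPKM + 0.1) placed it at 0.352 and called 7467 and 4288. With DESeq2 size factors the median was 0.194.

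Among the lists, genes of the 2-cell stage (zygotic activation) rose, with 32 of 39 members higher and 5 lower and a median log2 change of 4.48 (camera, adjusted p = 3.83e-18, but adjusted p = 0.113 with an estimated correlation). Gm2016 rose 80.7-fold, from 29.4 ± 48.4 to 2630 ± 741 cRPKM (SD, n = 4), and Gm5662 was at least 225-fold higher, both being members of repeated families with uncertain counts. The 1-cell SD of Gm2016 exceeded its mean, so that level was uneven among the 4 libraries and its fold depends on this. Arg2, an arginase, fell 4.62-fold and Nelfa, of the elongation factor NELF, fell 1.26-fold. Later-embryo lineage markers rose too (15 of 20 higher, 3 lower, median 2.40, adjusted p = 0.000878, but adjusted p = 0.229 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, rose 9.75-fold from 4.79 ± 0.297 to 55.3 ± 18.9 cRPKM, Tfap2c fell 2.23-fold, and Pou5f1, the pluripotency factor OCT4, did not pass (227 ± 15.5 and 270 ± 34.5 cRPKM, adjusted p = 0.916).

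p53 target genes rose as a list (20 of 32 higher, 5 lower, median 0.83, adjusted p = 0.0138, but adjusted p = 0.39 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 13.1-fold from 4.52 ± 0.972 to 69.8 ± 21.7 cRPKM (SD, n = 4, log2 3.66, SE 0.23, adjusted p = 3.5e-07). Mdm2, the ubiquitin ligase of p53, rose 1.73-fold and Ei24 1.74-fold. Rrm2b did not pass (adjusted p = 0.666), and Ercc5, which is also in the excision repair list, fell. Trp53, p53 itself, is in the DNA damage signalling list and fell 3.99-fold from 50.7 ± 4.53 to 15.3 ± 2.01 cRPKM (named after its values were seen).

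Genes of the DNA damage response and DNA repair fell in larger numbers than they rose. Of the DNA damage signalling list 23 of 37 fell and 10 rose (median −1.09, adjusted p = 0.000852, but adjusted p = 0.229 with an estimated correlation). Chek1, the checkpoint kinase 1, fell 3.28-fold from 357 ± 13.0 to 130 ± 9.96 cRPKM (SD, n = 4), Rnf8, a ubiquitin ligase at double-strand breaks, fell 4.63-fold, and Tipin, which protects replication forks, rose 1.47-fold. End joining, excision and mismatch repair genes showed 34 of 46 lower and 6 higher (median −1.12, adjusted p = 6.85e-08, but adjusted p = 0.113 with an estimated correlation). The DNA glycosylase Neil3 fell 8.99-fold from 199 ± 14.4 to 26.6 ± 2.73 cRPKM, whereas Ddb1 rose 1.57-fold. Homologous recombination and Fanconi anaemia genes showed 28 of 35 lower and 5 higher (median −0.91, adjusted p = 5.1e-05, but adjusted p = 0.113 with an estimated correlation), among them Ube2t (7.13-fold lower) and Sfr1 (2.6-fold lower).

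Oocyte and maternal-effect genes fell (48 of 70 lower, 18 higher, median −1.20, adjusted p = 5.9e-08, but adjusted p = 0.229 with an estimated correlation). Obox1, an oocyte homeobox gene, fell 3.59-fold from 4660 ± 398 to 1560 ± 196 cRPKM (SD, n = 4). Tcl1, a coactivator of AKT, rose 3.44-fold and Btg4, an adaptor of the CCR4-NOT deadenylase, 1.71-fold, while Dppa3 did not pass (adjusted p = 0.606). Proteasome genes fell (24 of 33 lower, 4 higher, median −1.18, adjusted p = 6.81e-06, but adjusted p = 0.436 with an estimated correlation), with the core subunit gene Psma7 8.79-fold lower, Psmb2 3.85-fold lower and the lid subunit gene Psmd3 2.77-fold higher. The snRNP-specific and LSm genes fell (24 of 37 lower, 11 higher, median −1.26, adjusted p = 7.81e-05, but adjusted p = 0.39 with an estimated correlation). Prpf6, of the U5 particle, fell 13.6-fold from 108 ± 9.47 to 9.49 ± 1.02 cRPKM, Snrnp27 fell 2.44-fold, and Snrpc, of the U1 particle, rose 14.6-fold from 7.3 ± 1.37 to 127 ± 22.6 cRPKM. Cell cycle regulators (25 of 47 lower, 17 higher, median −0.62, adjusted p = 0.00939, but adjusted p = 0.298 with an estimated correlation) included Ccnb1, cyclin B1, 2.81-fold lower, and Aurkc, an Aurora kinase of meiosis, 4.7-fold lower. Zygotic housekeeping activation genes fell despite their name (26 of 42 lower, 10 higher, median −0.89, adjusted p = 0.00297, but adjusted p = 0.426 with an estimated correlation). Among them the nucleolar protein gene Nop56 fell 8.86-fold, the helicase gene Eif4a1 fell 2.99-fold, and Eif4e rose 1.35-fold.

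The other 12 lists did not pass camera for the stage effect. Members still changed singly: ribosomal proteins 31 up and 5 down of 64 (median 0.70, adjusted p = 0.166), with Rpl17 2.66-fold lower, and snRNP assembly 9 up and 6 down of 17 (0.55, adjusted p = 0.471), with Riok1, of the PRMT5 complex, 7.26-fold lower and Smn1 3.55-fold lower. Sm core genes went 2 up and 2 down of 7 (median −0.35, adjusted p = 0.687), Snrpg being 5.87-fold higher and the injected Snrpb (log2 −1.63, SE 1.31) and Snrpd2 (−0.35, SE 0.64) not passing (adjusted p = 0.289 and 0.638). The hnRNP list had 7 up and 11 down of 26 (median −0.19, mean 0.104, adjusted p = 0.823), with Pcbp1 lower (527 and 322 cRPKM, adjusted p = 1.34e-05), SR proteins 3 up and 5 down of 16 (−0.12, adjusted p = 0.76), with Srsf2 1.97-fold lower, and the stress response list 12 up and 15 down of 34 (−0.08, mean 0.441, adjusted p = 0.837), with Creld2 2.09-fold lower. The medians of the last 3 lists turned positive with library totals (0.067, 0.142 and 0.182). Nonsense-mediated decay genes went 3 up and 11 down of 16 (median −0.71, adjusted p = 0.0853), with Magoh 1.6-fold lower, apoptosis genes 12 up and 10 down of 30 (0.24, adjusted p = 0.635), with Birc3 3.51-fold lower, and interferon genes 9 up and 8 down of 23 (0.38, adjusted p = 0.823), with Irf1 2.48-fold lower. Adjusted over the list alone, the stage counts of all 23 lists were the same except for the stress response list (13 up).

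Markers of other cells were followed as a measure of carry-over. Their stage changes do not tell carry-over from expression of the same genes by the embryo, which was not tested. Cumulus and granulosa cell markers went 7 up and 6 down of 21 (median −0.52, adjusted p = 0.823). Taken within each injection, the list's stage change had medians of 0.564 (−0.26 to 1.508) with mCherry and −0.62 (−2.532 to 0.704), −0.277 (−1.29 to 1.199) and −1.514 (−3.03 to −0.13) with Snrpb, Snrpd2 and both. The 4 intervals overlap, but they are over members of the same list, so the overlap does not test a difference. The direct test for injected against control libraries is given below under stage dependence. Cyp19a1, the aromatase gene, fell 5.41-fold from 17.7 ± 1.7 to 3.92 ± 0.491 cRPKM (SD, n = 4). Cyp19a1 and Nr5a2 had reads in all 8 libraries. Blood, fibroblast and oviduct markers had 8 up and 1 down of 10 (median 3.57, adjusted p = 0.0563), with Lyz2 176-fold higher (68.4 to 648) and Epcam 38-fold higher, and sperm markers 7 up and 0 down of 13 (1.54, adjusted p = 0.182), with Odf2 4.43-fold higher.

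**Figure D2:**
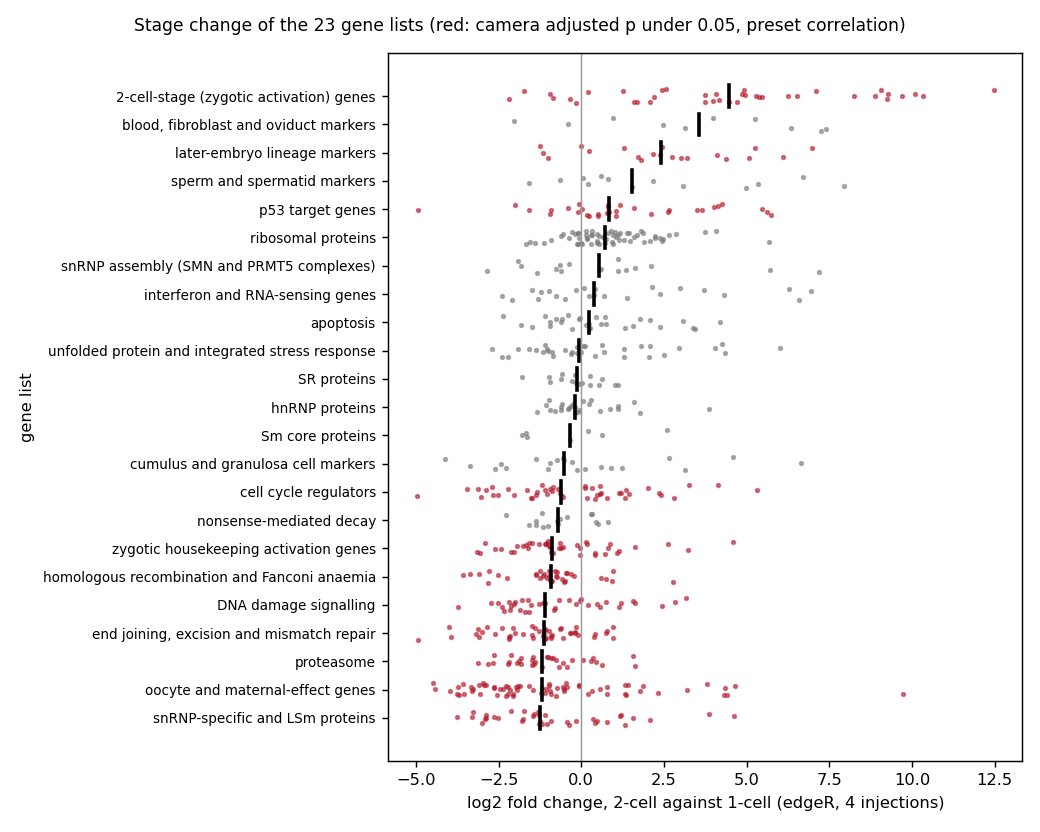
Fitted log2 fold change between the 2-cell and 1-cell stages over the 4 injections (horizontal axis) for each member of the 23 gene lists (vertical axis), with a black bar at the list median. Red points mark the 11 lists with a camera adjusted p under 0.05 at the preset correlation, from the 2-cell-stage genes (median 4.48) to the snRNP-specific and LSm proteins (median −1.26).

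The next comparison asked which transcripts differed 5 h after injection of either or both Sm mRNAs. In the 1-cell library given both, the 10 higher genes ranked first against mCherry included 3 cumulus cell markers. Tnfaip6, a hyaluronan-binding protein of the expanding cumulus, was 7.66-fold higher (95% interval 6.22 to 9.51, 713 against 103 reads), Ptgs2, a prostaglandin synthase, 8.31-fold (6.26 to 11.2), and Fst, follistatin, 10.6-fold (8.06 to 14.1). Lox, a lysyl oxidase, was 75.8-fold higher (20.6 to 632, 137 against 2 reads), Sfrp4, a WNT antagonist, 66.9-fold (18.1 to 559), and Abca1, a lipid transporter, at least 20.7-fold (56 against 0 reads). Trabd (18.5-fold, 6.91 to 70), Crim1 (9.29-fold, 6.76 to 13.1), Spsb1 (8.51-fold, 6 to 12.4) and the desaturase gene Scd2 (6.9-fold, 6.05 to 7.88) completed the 10. Lower levels were found for Tdgf1, a Nodal co-receptor (8.74-fold, 4.4 to 19.7, 9 against 87 reads), Sall3 (7.32-fold, 3.78 to 15.8), Sema6b (4.52-fold), Uts2b (3.9-fold), Olfr221 (3.07-fold), Mtrf1l (2.84-fold), Tmx4 (2.71-fold), Scnn1b (2.5-fold), Coq6 (2.23-fold) and Cdo1, cysteine dioxygenase (2.19-fold, 2.15 to 2.23, 16187 against 39209 reads). The rule for named genes required the same side of the shared mCherry library in both single injections, which some genes met narrowly (Sall3, log2 −0.05 with Snrpd2).

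With Snrpb alone at the 1-cell stage, the first 3 higher genes were Ctsk, cathepsin K (at least 437-fold, 1321 against 0 reads), Sfrp2 (207-fold, 36.8 to 8230, 209 against 1 read) and Lox (91.8-fold, 25.1 to 764), and the first 3 lower ones Ppp2r2c (15.8-fold, 6.99 to 44.1), Nlrp12 (8.47-fold, 4.38 to 18.3) and Fat4 (6.89-fold, 3.74 to 13.9). With Snrpd2 alone they were Wnt7b (39.1-fold, 10.4 to 329), Tdrd6 (17.9-fold, 8.85 to 42.4) and Sfrp4 (32.2-fold, 8.54 to 272), and Sema3f (13.5-fold, 5.5 to 42.7), Tdgf1 (5.89-fold, 3.33 to 11.2) and Spats2l (4.24-fold, 2.68 to 6.99). The rule for single injections did not ask the other libraries to move alike. Ctsk had 4 reads with Snrpd2 and 4 with both, and Sfrp2 had 19 and 0. The rises of Ctsk and Sfrp2 were thus not seen in the combined library, which also received Snrpb mRNA, whereas Lox had 51 and 137 reads. At least 2-fold differences from mCherry numbered 394 higher and 151 lower of 11703 genes for Snrpb (320 and 210 with library totals), 422 and 175 of 11560 for Snrpd2, and 381 and 104 of 11671 for both. Sampling of reads alone gave on average 2.0, 0.6 and 1.2 such genes in these comparisons, both directions together. When the 3 injected libraries were tested together against the lone control, edgeR called 0 genes, with 2618 at an unadjusted p under 0.05 and a smallest adjusted p of 0.146. DESeq2 called 420 higher and 114 lower, limma on log2(cRPKM + 0.1) called Gm13128 lower (−5.61, adjusted p = 0.0126), a gene of a repeated family, and limma on log2(cRPKM + 1) called 0. Without the 1-cell Snrpd2 library, edgeR called Spp1 (2.46, adjusted p = 0.0366) and Tnfaip6 (2.75, adjusted p = 0.0455), and without the combined library Akt1, Rragc and Tcl1 (1.47, 1.48 and 1.43), genes chosen after their values were seen.

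At the 1-cell stage 8 lists stood apart in camera, although 0 of their genes passed over all genes (edgeR). Ribosomal protein genes were lower (67 members, median −0.41, adjusted p = 9.25e-06, but adjusted p = 0.67 with an estimated correlation). Their medians were −0.534 (−0.592 to −0.386), −0.6 (−0.737 to −0.361) and −0.351 (−0.422 to −0.257) with Snrpb, Snrpd2 and both, below all 10000 matched random lists each time, and Rpl17 stood at 97.58 cRPKM with mCherry and 58.91, 57.08 and 78.05 cRPKM with the injections. The random lists were matched on expression but not on transcript length. Across genes the mean 1-cell ratio to mCherry had r = 0.193 with log2 length, so a part of a length trend in this ranking stays open. Proteasome genes were lower (33 members, median −0.27, adjusted p = 0.000368, but adjusted p = 0.67 with an estimated correlation), with 1 higher and 4 lower adjusted over the list alone. Psmb2 stood at 244.14 cRPKM with mCherry and at 157.19, 174.84 and 179.19 cRPKM, while Psmd3 went from 26.76 to 56.86, 82.05 and 50.28 cRPKM. Lower lists also were snRNP assembly (17 members, −0.31, adjusted p = 0.00754, but adjusted p = 0.498 with an estimated correlation, and −0.206 without the 1-cell Snrpd2 library), zygotic housekeeping activation (42 members, −0.18, adjusted p = 0.0101, but adjusted p = 0.67 with an estimated correlation, and −0.118 without the 1-cell combined library) and 2-cell-stage genes (40 members, median −0.16 but mean 0.032, adjusted p = 0.0138, but adjusted p = 0.498 with an estimated correlation).

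Cumulus and granulosa cell markers were higher in the injected 1-cell libraries (21 members, median 1.12, adjusted p = 0.000418, but adjusted p = 0.498 with an estimated correlation), 2 of them adjusted over the list alone. Their medians were 1.121 (0.472 to 2.085), 0.407 (0.006 to 1.072) and 1.675 (0.193 to 2.789) with Snrpb, Snrpd2 and both, at percentiles 100, 99.9 and 100 of matched random lists. Tnfaip6 stood at 1.17, 6.2, 4.23 and 9.11 cRPKM with mCherry, Snrpb, Snrpd2 and both, whereas Cyp19a1, which is abundant in every 1-cell library, stood at 15.52, 17.72, 19.65 and 18.08 cRPKM. Blood, fibroblast and oviduct markers had a median of 1.307 in the same fit (1.282 with library totals) but did not pass camera. Sm core genes were higher (7 members, median 0.73, adjusted p = 0.00354, but adjusted p = 0.498 with an estimated correlation), 2 of them adjusted over the list alone, and 5 members without Snrpb and Snrpd2 had a median of 0.42 (adjusted p = 0.0142, but adjusted p = 0.677 with an estimated correlation). Among these Snrpg stood at 43.42 cRPKM with mCherry and at 74.06, 126.64 and 84.63 cRPKM. The hnRNP genes were higher (26 members, median 0.18, adjusted p = 0.0175, but adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.0915 without the 1-cell Snrpd2 library), 1 of them adjusted over the list alone.

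Lists of the DNA damage response did not pass at the 1-cell stage (DNA damage signalling, median 0.004 but −0.021 with library totals, adjusted p = 0.95, and p53 targets, 0.058, adjusted p = 0.861). Nonsense-mediated decay genes had 5 higher adjusted over the list alone but missed the threshold as a list (0.124, adjusted p = 0.0507), and passed without the 1-cell Snrpb (adjusted p = 0.023), the 1-cell combined (0.0282), the 2-cell mCherry (0.0496) or the 2-cell Snrpd2 library (0.0441). Adjusted over the list alone, cell cycle regulators had 4 higher and 3 lower, oocyte and maternal-effect genes 2 higher and 1 lower, the stress response list 2 higher, and end joining, excision and mismatch repair and p53 targets 1 higher each. The other 13 lists had 0.

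The same comparison 24 h after injection, at the 2-cell stage, asked what raised Sm mRNA does once the embryonic genome is active. In the library given both mRNAs, the higher genes were led by Rassf2, a RAS-association protein gene (20.9-fold, 95% interval 9.31 to 58, 119 against 6 reads), the receptor phosphatase gene Ptpru (52.6-fold, 9.02 to 2120, 50 against 1 read), Tmem154 (31.0-fold, 8.22 to 262), Pcdhb2 (12.8-fold, 5.61 to 36) and Ccdc92b (10.4-fold, 5.03 to 24.9). Sfmbt2 (7.45-fold), Cd52 (6.27-fold), Xirp1 (9.12-fold) and Sparcl1 (8.02-fold) followed. The inhibin subunit genes Inha and Inhbb were lower, Inha at least 17.4-fold (0 against 55 reads) and Inhbb 18.1-fold (8.93 to 42.6, 8 against 152 reads). Both are in the list of cumulus and granulosa cell markers. These ratios do not tell carry-over of such cells from a response of the embryo. Rab3c (16.5-fold, 5.33 to 82.4), Best3 (12.2-fold), Dio2, a deiodinase gene (8.82-fold, 4.05 to 22.8), Smim10l2a (7.35-fold), Kcnmb1 (7.08-fold), Tectb (6.65-fold), Lox (5.7-fold, 3.49 to 9.82) and Fhl1 (5.53-fold) were lower too. Lox was thus on the other side of its control than at the 1-cell stage.

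With Snrpb alone at the 2-cell stage the first genes were Rassf2 (29.6-fold, 13.3 to 81.9), Ptpru (59.3-fold, 10.2 to 2380) and Gp1ba (55.1-fold, 9.47 to 2220) on the higher side, and Inha (26.4-fold, 6.98 to 224), Sectm1a (12.3-fold, 5.42 to 34.7) and Xkr4 (10.6-fold, 5.14 to 25.3) on the lower side. With Snrpd2 alone they were Hsd3b1, an enzyme of steroid synthesis (52.5-fold, 26.4 to 122, 466 against 8 reads), Akr1c18 (at least 26.1-fold, 87 against 0 reads) and Plxna3 (at least 15.9-fold), and Zfp112 (at least 19.6-fold lower, 0 against 53 reads), the follicle-stimulating hormone receptor gene Fshr (58.9-fold lower, 10.1 to 2370) and Lrrk1 (21.5-fold lower, 6.99 to 107). Inha, Hsd3b1 and Fshr are in the list of cumulus and granulosa cell markers, so carry-over was not told apart from a response of the embryo for them. Hsd3b1 had 5 reads in the combined library, which also received Snrpd2 mRNA, while Akr1c18 had 27 and Plxna3 17. At least 2-fold differences numbered 348 higher and 227 lower of 13156 genes for Snrpb, 369 and 207 of 13349 for Snrpd2, and 283 and 178 of 13134 for both. With the 3 injected libraries tested together, edgeR called 0 genes, with 637 at an unadjusted p under 0.05 and a smallest adjusted p of 0.8. DESeq2 and limma on log2(cRPKM + 1) called 0 and limma on log2(cRPKM + 0.1) called 2 higher, Gm13128 (6.69) and Pramef17 (2.25), both of repeated families. In simulated data of this comparison with 200 changed genes, 40% of 2-fold and 76% of 4-fold changes were recovered. Recovery with fewer changed genes was not simulated, so these shares do not show how many changes the 0 calls missed. Ptpru, for example, was not called at 59.3-fold, 53.1-fold and 52.6-fold higher with Snrpb, Snrpd2 and both, against 1 read with mCherry.

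No list passed camera for the 2-cell injections. The smallest adjusted p was 0.534, shared by ribosomal (median −0.067), maternal-effect (−0.05), p53 target (0.086), snRNP-specific and LSm (0.075) and housekeeping activation genes (0.075). Ribosomal genes split by injection, with medians of −0.257 (−0.315 to −0.144) for Snrpb, 0.193 (0.137 to 0.32) for Snrpd2 and −0.227 (−0.276 to −0.172) for both. Without the 2-cell Snrpd2 library they passed as lower at the preset correlation (−0.25, camera adjusted p = 0.00056). The value of that setting with an estimated correlation is not given here. DNA damage signalling genes were close to the control, with medians of 0.083, −0.032 and −0.048 for Snrpb, Snrpd2 and both at percentiles 94.2, 32.8 and 19.3 (camera median −0.009 but 0.033 with library totals, adjusted p = 0.972). Chek1 stood at 144.97 cRPKM with mCherry and at 128.04, 125.79 and 122.76 cRPKM with the injections, and Rnf8 at 27.83 against 28.24, 29.08 and 31.71 cRPKM. Homologous recombination genes had medians of 0.073, −0.06 and 0.08 (the middle one 0.021 with library totals) and end joining, excision and mismatch repair genes 0.1, −0.002 and 0.061. The p53 targets had medians of 0.051, 0.292 (−0.02 to 0.398) and 0.07, at percentiles 76.8, 100 and 85.5, and Cdkn1a stood at 66.86 cRPKM with mCherry and at 53.65, 101.18 and 57.45 cRPKM. The 2-cell-stage list (−0.062, 0.024 and −0.005) and the maternal-effect list (−0.076, −0.037 and −0.043) lay near 0. Over all genes 0 list members passed, and adjusted over the list alone 1 cumulus and granulosa cell marker was lower and 0 genes of the other 22 lists passed.

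**Figure D3:**
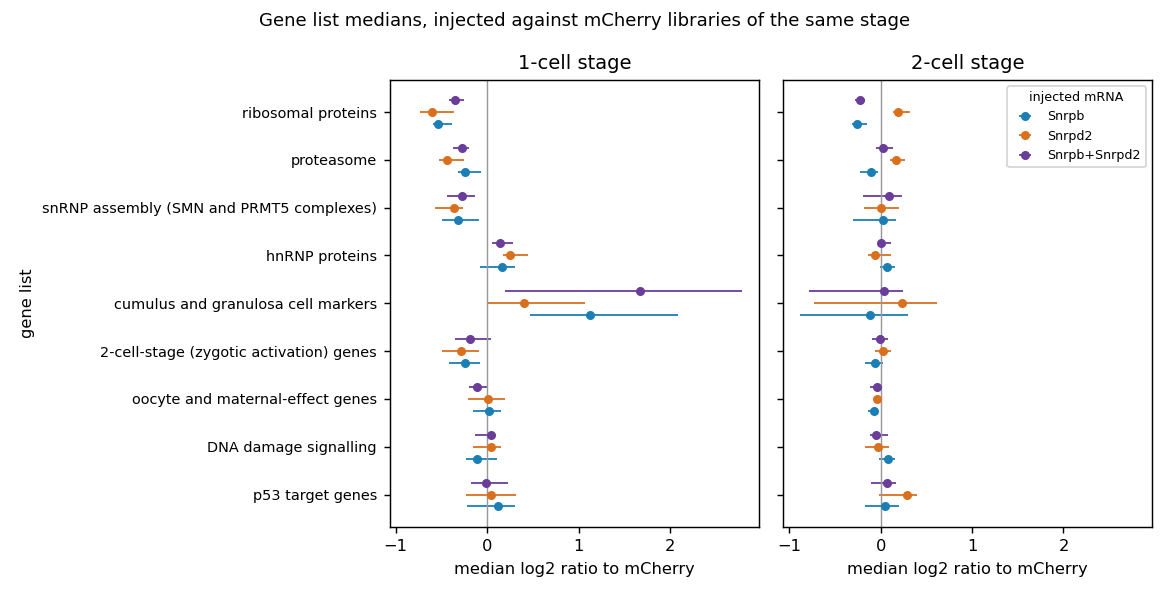
Median log2 ratio of each injected library to the mCherry library of its stage (horizontal axis) for 9 gene lists (vertical axis), with the order-statistic interval over list members as bars, at the 1-cell (left) and 2-cell stage (right). Ribosomal protein genes lie below 0 in all 3 injections at the 1-cell stage (−0.534, −0.6 and −0.351) and cumulus markers above it (1.121, 0.407 and 1.675).

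Whether the effect of an injection differed between stages was tested directly. For stage dependence edgeR called 0 genes (1648 at an unadjusted p under 0.05, smallest adjusted p of 0.381), DESeq2 called 8 higher and 23 lower, limma on log2(cRPKM + 0.1) called 1, Gm13128 (12.30), and limma on log2(cRPKM + 1) called 0. Of the 23 lists, 8 differed between stages at the preset correlation, with ribosomal protein, proteasome and snRNP assembly genes relatively higher at the 2-cell stage (medians 0.306, 0.337 and 0.329) and cumulus markers and Sm core genes relatively lower (−0.99 and −0.886). With an estimated correlation 0 lists passed, the smallest being adjusted p = 0.813. The ribosomal median was 0.13 (adjusted p = 0.0807) without the 2-cell Snrpd2 library, the cumulus median −0.484 without the 1-cell combined library and the Sm core median −0.803 (adjusted p = 0.0996) without the 2-cell Snrpb library.

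Each injection was then taken over both stages, to ask what Snrpb, Snrpd2 and their combination had in common at 5 h and 24 h. The injected Snrpd2 was the gene that passed. With Snrpd2 mRNA, edgeR called 1 gene, Snrpd2 (log2 10.85, SE 1.12, adjusted p = 0.0399, 497 genes at an unadjusted p under 0.05), which did not pass without the 1-cell Snrpb library, and DESeq2 also called Trim62 (1.31). With both mRNAs edgeR called 0 genes (506 at an unadjusted p under 0.05), although Snrpd2 (10.09, SE 1.09) came close with adjusted p = 0.0573 and passed without any 1 of the 1-cell Snrpd2 (adjusted p = 0.0201), 1-cell combined (0.00304), 2-cell mCherry (0.0122), 2-cell Snrpd2 (0.0144) and 2-cell combined libraries (0.00282). DESeq2 called Snrpd2 and Cd52 (2.53). With Snrpb mRNA edgeR called 0 genes (583 at an unadjusted p under 0.05) and DESeq2 0. Snrpb itself, whose excess differed strongly between the stages, had a log2 change of 9.91 (SE 1.91, adjusted p = 0.947). The combined injection differed from Snrpb alone in 1 gene, Snrpd2 (11.18, SE 1.15, adjusted p = 0.0364). The combined injection and Snrpd2 alone differed in 0 genes (edgeR, 240 at an unadjusted p under 0.05, and 0 with DESeq2 and limma), and Snrpb alone differed from Snrpd2 alone in Snrpd2 (−11.94, SE 1.18, adjusted p = 0.0259). These 2 calls of Snrpd2 were lost without the 1-cell Snrpb library (0 genes, smallest adjusted p = 1 and adjusted p = 0.889) and without the 2-cell Snrpb library. Each of these settings left 1 library for Snrpb, with the spread taken from the other injections, so the other genes called there (1 for Snrpb, 2 and 1 for these 2 comparisons) are not read as effects of Snrpb. The genes besides Snrpb and Snrpd2 were named after their values were seen.

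Gene lists were tested in the same average over both stages (camera). With Snrpb 4 lists were called, and each had adjusted p = 0.845 with an estimated correlation. Ribosomal protein genes had a median of −0.39 (adjusted p = 1.22e-08), and −0.212 (adjusted p = 0.0542) without the 1-cell mCherry library. Cumulus markers had 0.30 (adjusted p = 0.00543), with ratios to mCherry of 1.121 at the 1-cell and −0.118 (−0.884 to 0.303) at the 2-cell stage. Their value hung on the mCherry libraries more than on either Snrpb library. They stood at −0.014 (adjusted p = 0.921) without the 1-cell mCherry, 0.241 (adjusted p = 0.0914) without the 1-cell Snrpb, 0.238 (adjusted p = 0.103) without the 2-cell Snrpb and 1.33 without the 2-cell mCherry library. Proteasome genes had −0.15 (adjusted p = 0.0146), with −0.033 (adjusted p = 0.978) without the 1-cell mCherry, −0.031 (adjusted p = 0.933) without the 2-cell Snrpb, −0.234 without the 1-cell Snrpb and −0.326 without the 2-cell mCherry library. Housekeeping activation genes had −0.12 (adjusted p = 0.031), with 0.044 (adjusted p = 0.994) without the 1-cell mCherry, −0.129 (adjusted p = 0.0914) without the 1-cell Snrpb, −0.115 (adjusted p = 0.476) without the 2-cell Snrpb and −0.19 without the 2-cell mCherry library.

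With Snrpd2 6 lists were called over both stages, and none with an estimated correlation. Ribosomal protein genes had −0.19 (adjusted p = 0.0188, but adjusted p = 0.837 with an estimated correlation). This value came from the 1-cell library, since the ratios were −0.6 at the 1-cell and 0.193 at the 2-cell stage, and the list turned to 0.215 without the 1-cell Snrpd2 and 0.075 (adjusted p = 0.944) without the 1-cell mCherry library (−0.527 without the 2-cell Snrpd2 and −0.369 without the 2-cell mCherry library). Sm core genes had 0.42 (adjusted p = 7e-08, but adjusted p = 0.37 with an estimated correlation). With Snrpb and Snrpd2 left out the list had 0.391 (camera, adjusted p = 0.00485, but adjusted p = 0.669 with an estimated correlation). The full list had 0.381, no longer past the threshold, without the 2-cell Snrpd2, 0.163 without the 1-cell mCherry and 0.948 without the 2-cell mCherry library. Nonsense-mediated decay genes had 0.16 (adjusted p = 0.0188, but adjusted p = 0.547 with an estimated correlation), and did not pass without the 1-cell mCherry (adjusted p = 0.251), 1-cell Snrpd2 (adjusted p = 0.108), 2-cell mCherry (adjusted p = 0.0656) or 2-cell Snrpd2 library (adjusted p = 0.106). For hnRNP (0.12), SR (0.20) and snRNP assembly genes (−0.15), each at adjusted p = 0.0343, the value was adjusted p = 0.737 with an estimated correlation. The hnRNP list, with ratios of 0.244 at the 1-cell and −0.064 at the 2-cell stage, had 0.097 (adjusted p = 0.471) without the 1-cell mCherry, 0.054 (adjusted p = 0.836) without the 1-cell Snrpd2 and 0.284 without the 2-cell Snrpd2 library. The SR list had 0.186 (adjusted p = 0.488) without the 1-cell mCherry and 0.115 (adjusted p = 0.341) without the 2-cell Snrpd2 library. The snRNP assembly list, with ratios of −0.363 and 0.008 at the 2 stages, turned to 0.036 (adjusted p = 0.944) without the 1-cell mCherry and 0.047 (adjusted p = 0.556) without the 1-cell Snrpd2 library. It had −0.105 (adjusted p = 0.0645) without the 1-cell combined, −0.23 without the 2-cell Snrpd2 and −0.372 without the 2-cell mCherry library.

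With both mRNAs 3 lists were called over both stages. Ribosomal protein genes had −0.26 (adjusted p = 1.21e-05, but adjusted p = 0.892 with an estimated correlation), with −0.057 (adjusted p = 0.617) without the 1-cell mCherry, −0.158 (adjusted p = 0.261) without the 2-cell combined and −0.442 without the 2-cell mCherry library. Cumulus markers had 0.48 (adjusted p = 0.000425, but adjusted p = 0.892 with an estimated correlation), with ratios of 1.675 at the 1-cell and 0.039 (−0.785 to 0.249) at the 2-cell stage. They stood at 0.301 (adjusted p = 0.709) without the 1-cell mCherry, 0.136 (adjusted p = 0.703) without the 1-cell combined, 0.721 without the 2-cell combined and 1.392 without the 2-cell mCherry library. Sm core genes had 0.14 (adjusted p = 1.21e-05, but adjusted p = 0.553 with an estimated correlation), a call that rested on the injected genes, since adjusted p = 0.702 with Snrpb and Snrpd2 left out. This list had 0.063 (adjusted p = 0.709) without the 1-cell mCherry, 0.061 without the 1-cell combined, 0.255 without the 2-cell combined and 0.581 without the 2-cell mCherry library. Without the 1-cell mCherry library 0, 2 and 0 lists were called for Snrpb, Snrpd2 and both, and without the 2-cell mCherry library 8, 8 and 7. Leaving out a library of the injection in question left 1 library for it, with the spread taken from the other injections.

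Injected libraries were also compared with each other. At the 1-cell stage, 187 genes were at least 2-fold higher and 64 lower with Snrpb than with Snrpd2, 159 and 122 with both than with Snrpb, and 253 and 50 with both than with Snrpd2. At the 2-cell stage the numbers were 349 and 456, 211 and 226, and 242 and 313. These counts have no replicate check.

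The change from the 1-cell to the 2-cell stage was also taken within each injection. At least 2-fold changes numbered 3729 higher and 3335 lower of 13282 genes with mCherry, 3580 and 3248 of 13359 with Snrpb (4329 and 2424 with library totals), 3637 and 3079 of 13451 with Snrpd2 (4301 and 2180 with library totals), and 3512 and 3202 of 13251 with both. The 2-cell-stage list had medians of 4.182, 4.649, 4.821 and 4.068 with mCherry, Snrpb, Snrpd2 and both, and the maternal-effect list −1.148, −1.348, −1.373 and −1.07. Across 13525 genes, the slope of each injection's stage change on that of the others was 0.996 (mCherry), 0.989 (Snrpb), 0.976 (Snrpd2) and 0.937 (both), with standard errors over genes of 0.0049, 0.005, 0.0048 and 0.0046. With cRPKM the slopes were 0.991, 0.978, 0.985 and 0.972. Genes are not independent replicates, so these errors do not cover differences between pools.

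The last comparison asked how alike the injections were relative to mCherry. Across 11887 genes at the 1-cell stage, the ratios to mCherry had r = 0.719 for Snrpb and Snrpd2, 0.711 for Snrpb and both, and 0.716 for Snrpd2 and both. Unchanged libraries that share a control gave a simulated r of 0.5, 0.501 and 0.501. The covariances were 0.2177, 0.2051 and 0.2026 against simulated values of 0.0853, 0.0857 and 0.0856. Shared 2-fold genes numbered 149 higher and 51 lower for Snrpb and Snrpd2 (8.7 and 2.3 for independent lists), 169 and 34 for Snrpb and both (7.7 and 1.4), and 123 and 43 for Snrpd2 and both (8.6 and 1.6). Unchanged libraries against 1 control shared on average 45.6 and 46.2, 42.8 and 48.1, and 42.9 and 47.2 such genes in the simulation, and the observed shared lower genes were above that value for 1 pair and below it for the other two. At the 2-cell stage, across 13620 genes, r was 0.361, 0.566 and 0.469 against 0.501 simulated, and the covariances 0.0865, 0.1294 and 0.1069 against 0.1117, 0.1123 and 0.1122. Shared 2-fold genes there numbered 93 higher and 45 lower (4.7 and 3.6 for independent lists), 98 and 47 (3.6 and 3.1), and 92 and 52 (3.5 and 2.8). The simulation of unchanged libraries gave 84.8 and 91.5, 79.1 and 93.6, and 85.9 and 94.1. At the 2-cell stage 2 of the 3 covariances and all 3 numbers of shared lower genes thus lay below the simulated values. The simulation used the fitted dispersion, which holds the differences between the 3 injections. Its values are therefore not those of a shared control with no effect, and lying above or below them is not read as an effect or its absence. With a single control per stage the control could not be split, and part of the excess at the 1-cell stage may come from it.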

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

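The tests of whether the 1-cell mCherry pool lay earlier in the stage change, of a general rise of genes with few reads, of a single follicle cell source and of other splits of the 8 libraries were chosen only after the results they bear on had been seen, and the tests of a length or GC trend and of chance among genes with few reads were chosen before.

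Gene lists whose ratio of injected to control libraries differed between the 2 stages, by a camera test at the preset correlation, are given here with their values. The single 1-cell and 2-cell controls enter this difference, and no call held with an estimated correlation. The median log2 difference was 0.306 for ribosomal protein genes (adjusted p = 0.00622, but adjusted p = 0.842 with an estimated correlation, and 0.13 with adjusted p = 0.0807 without the 2-cell Snrpd2 library). It was 0.337 for proteasome genes (adjusted p = 0.0026, but adjusted p = 0.818 with an estimated correlation), 0.329 for snRNP assembly genes (adjusted p = 0.0188, but adjusted p = 0.813 with an estimated correlation) and 0.252 for zygotic housekeeping activation genes (adjusted p = 0.00363, but adjusted p = 0.818 with an estimated correlation, and 0.163 without the 2-cell Snrpd2 library). The 2-cell-stage list had a median of 0.238 against a mean of −0.047 (adjusted p = 0.0346, but adjusted p = 0.813 with an estimated correlation, 0.169 with adjusted p = 0.0564 without the 2-cell Snrpd2 library and 0.146 without the 1-cell Snrpd2 library). The snRNP-specific and LSm genes had 0.14 (adjusted p = 0.0394, but adjusted p = 0.818 with an estimated correlation, 0.135 with adjusted p = 0.0953 without the 1-cell combined library, 0.032 with adjusted p = 0.196 without the 2-cell Snrpd2 library and 0.228 without the 2-cell Snrpb library). Cumulus and granulosa cell markers had −0.99 (adjusted p = 0.00462, but adjusted p = 0.813 with an estimated correlation, with medians from −1.22 without the 1-cell Snrpd2 library to −0.484 without the 1-cell combined library), and Sm core genes, which include the injected ones, −0.886 (adjusted p = 0.0266, but adjusted p = 0.813 with an estimated correlation, and −0.803 with adjusted p = 0.0996 without the 2-cell Snrpb library). SR genes passed only without the 2-cell Snrpd2 library (−0.248, adjusted p = 0.0477, against adjusted p = 0.287 with it). Over all genes 0 members passed (edgeR), and adjusted over the list alone 2 cumulus markers, 2 Sm core genes and 1 gene each of the maternal-effect, p53 and SR lists were lower and 1 snRNP assembly gene was higher. No condition had enough libraries for a test of single samples that stand apart.

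The stage effect itself was set against other splits of the 8 libraries into 4 and 4 with the injection terms kept. Because those terms pair the 2 libraries of each injection, 8 splits part every pair, which is too few for a share under 0.05 (the smallest is 0.125). The real split, 1 of the 8, gave 11396 genes and the highest of the others 0. In the other splits the large stage difference counts as spread, which by itself keeps calls low, so their 0 carries no information on chance.

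The 1-cell mCherry library stood apart from the other 1-cell libraries. Its r with Snrpb, Snrpd2 and both was 0.9837, 0.9851 and 0.9845, against 0.9869, 0.9866 and 0.9878 among those 3. At least 2-fold differences from it, the same way in all 3 injections, were counted for 149 genes (131 higher, 18 lower). The rule differed from that for shared pairs, under which Snrpd2 and both shared 123 higher genes, fewer than the 131. A shared control gives some shared genes by itself, and the number expected from it was not simulated for the 149 genes. A trend with gene length or GC content was argued against as the source of these genes. Removing the medians of 100 length and GC bins raised the 149 to 171, a change of −14.8% in the sense of fewer genes (11748 genes, 98.8% with a length and GC value). Across these genes the mean ratio had r = 0.193 with log2 length and −0.021 with GC. A weak length trend over all genes therefore stays open, and the random lists were matched on expression but not on length. A control pool that lay earlier in the passage to the 2-cell stage may contribute, since the 1-cell ratios of one injection had a median r of 0.117 across 13525 genes (0.074 to 0.199 over 6 ordered pairs sharing no library) with the stage change of another, and 0.27 (0.088 to 0.327) across 8639 genes with at least 200 reads in all 4 1-cell libraries, a set chosen afterwards. Against it, 2-cell-stage genes were lower in the injected libraries (medians −0.246, −0.288 and −0.189), and r just above the bound of 0.1 set for that test was not read as deciding. An effect shared by all 3 Sm injections, which the design offers as the biological explanation, cannot be told apart from a difference of this 1 control pool, because it is the single 1-cell control analysed here.

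Cumulus and granulosa cell markers were higher in all 3 injected 1-cell libraries. A general rise of genes with few reads was argued against, since the list lay at percentile 99.9 or above among random lists matched on expression in each library. Carry-over of follicle cells of 1 fixed composition stays open, because the excess of 18 markers in the Snrpb and combined libraries departed from a single ratio with a chi-square per degree of freedom of 30.2 on counting error alone but of 0.54 once the fitted dispersion was added (17 degrees of freedom), and nothing in 2 single libraries shows which error applies. The abundant marker Cyp19a1, with reads in every library, stood at 15.52 cRPKM with mCherry and at 17.72, 19.65 and 18.08 cRPKM with the injections, and its high level would hide a small share. Blood, fibroblast and oviduct markers had a median of 1.307 in the 1-cell injected libraries without passing camera, so a rise particular to cumulus markers was not shown. An effect of the injected mRNAs was not tested apart from carry-over.

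Snrpd2 reads were lower in the Snrpb libraries than with mCherry at both stages (13 against 27 and 54 against 115 reads). Of 591 genes with similar control reads, 2 (0.34%) were as low or lower at both stages, while 74 were so at the 1-cell stage and 33 at the 2-cell stage, each taken alone. The joint share lay under the bound set beforehand for chance among genes with few reads. A share that must meet 2 conditions at once is small even where the stages are unrelated, so it cannot exclude chance. Snrpb in the Snrpd2 libraries went opposite ways, at 0.784 and 1.42 times the mCherry value. An effect of the injected Snrpb mRNA, which the design offers as the biological explanation, was not tested, and the 1-cell control pool is 1 of the 2 controls this rests on. Other technical explanations were not tested.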

How the results depend on the processing

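The tests without Ccdc82, the ratio medians of the Sm core list stripped of the injected genes and the values on genes with 200 reads in all 4 1-cell libraries were chosen only after the data had been seen, and the others were planned. Of the alternative values for counts, slopes and similarities, 678 stayed within their limits and 120 moved. Among named genes and single lists, 1382 were the same, 76 were weaker, 17 moved and 1 reversed. The direction of every stage call that was also called under another setting was kept, and Col5a2 alone of the named stage genes lost its call, with limma at either pseudocount. The stage effect was paired by injection, and without the injection term 5934 genes were higher and 5473 lower. Comparisons by replicate number were not made, since each condition had 1 library. Depth limited the genes with few reads, for which a count of 0 allows up to 3 reads, and the lack of replicate pools limited all comparisons of injections. Where no cause is given, the cause was not tested.

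Genes called higher with both mRNAs over both stages numbered 1 with DESeq2 size factors, library totals, no filter, limma at either pseudocount or Ccdc82 left out, and 2 with the DESeq2 test, against 0 in edgeR. For Snrpd2 alone 2 were called with the DESeq2 test. With Snrpb and Snrpd2 left out, 0 were called for Snrpd2, 0 for both against Snrpb and 0 for Snrpb against Snrpd2, because the called gene was Snrpd2 itself. DESeq2 called 420 higher and 114 lower for any injection at the 1-cell stage and 8 higher and 23 lower for stage dependence, where edgeR called 0. Limma on log2(cRPKM + 0.1) called 1 lower at the 1-cell stage, 2 higher at the 2-cell stage and 1 higher for stage dependence. Lists called with an estimated correlation numbered 0 for the stage effect, 0 for the 1-cell injections, 0 for stage dependence, 0 for Snrpb, 0 for Snrpd2 and 0 for both.

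Counts of genes apart from mCherry changed with the thresholds by construction. In the order Snrpb, Snrpd2 and both, a 1.5-fold threshold gave 1133, 1400 and 1040 higher and 759, 1118 and 576 lower at the 1-cell stage, and 1073, 1120 and 922 higher and 792, 656 and 615 lower at the 2-cell stage. A 3-fold threshold gave 133, 65 and 167 higher and 23, 24 and 10 lower at the 1-cell stage, and 89, 111 and 84 higher and 59, 56 and 49 lower at the 2-cell stage. A minimum of 20 reads gave 695 (Snrpb) and 666 (both) higher and 362, 396 and 275 lower at the 1-cell stage, and 661, 682 and 566 higher and 523, 492 and 457 lower at the 2-cell stage. A minimum of 200 reads gave 143 (Snrpb) and 126 (both) higher and 33, 41 and 14 lower at the 1-cell stage, and 72, 87 and 49 higher and 36, 20 and 23 lower at the 2-cell stage. For the stage change within mCherry, Snrpb, Snrpd2 and both, 3-fold lower genes numbered 1838, 1790, 1595 and 1698, and 2-fold higher genes at 200 reads 2332, 2190, 2207 and 2162.

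Progress slopes with cRPKM were 0.978 (Snrpb) and 0.972 (both), with 20 reads 0.983 (mCherry), 0.965 (Snrpd2) and 0.924 (both), and with 200 reads 1.016 (mCherry) and 0.988 (Snrpd2). The similarity r at the 1-cell stage was 0.744 (Snrpb and Snrpd2) and 0.737 (Snrpd2 and both) with cRPKM, and 0.792, 0.722 and 0.801 with 200 reads. At the 2-cell stage it was 0.319 and 0.439 with cRPKM, and 0.202, 0.611 and 0.365 with 200 reads. The ribosomal median for 1-cell Snrpb was −0.628 with library totals and −0.631 with cRPKM ratios.

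With each library left out in turn, stage calls ranged from 5569 to 5874 higher and 4680 to 5270 lower. Genes called ranged from 0 to 3 higher for any injection at the 1-cell stage, 0 to 1 higher for Snrpb, 0 to 1 for Snrpd2, 0 to 1 for both, 0 to 1 higher and 0 to 2 lower for both against Snrpb, and 0 to 1 higher and 0 to 1 lower for Snrpb against Snrpd2. Lists called ranged from 0 to 1 for the 2-cell injections, 0 to 8 for Snrpb, 2 to 8 for Snrpd2 and 0 to 7 for both. The ribosomal list under Snrpd2 over both stages ran from adjusted p = 7.69e-10 to adjusted p = 0.944, with medians from −0.527 to 0.215, and reversed without the 1-cell Snrpd2 library, which left the 2-cell Snrpd2 library to set its value.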

Other observations

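The values in this part were chosen only after they had been seen, and no tests of a hypothesis were run on them beyond the planned camera tests of the lists.

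Of the gene lists in the 2-cell library given Snrpd2 alone, 5 were picked for their high percentiles. Against the 2-cell mCherry library their medians were 0.169 (0.104 to 0.264 over list members) for proteasome and 0.145 (0.059 to 0.225) for housekeeping activation genes. Intervals that reached below 0 went with 0.184 (−0.087 to 0.295) for SR, 0.112 (−0.081 to 0.257) for stress response and 0.292 (−0.02 to 0.398) for p53 target genes. Among random lists matched on expression the first 4 lay at percentile 99.9 and p53 targets at percentile 100, and no list passed camera for the 2-cell injections. In the same order the medians were −0.109, −0.032, −0.171, −0.088 and 0.051 with Snrpb alone, and 0.025, 0.097, −0.066, 0.044 and 0.07 with both mRNAs, of which housekeeping activation lay at percentile 98.3. Cdkn1a stood at 101.18 cRPKM with Snrpd2 against 66.86 with mCherry, Srsf2 at 91.26 against 73.77, Hspa5, the chaperone BiP, at 131.51 against 104.04, and Psmd4 at 143.21 against 115.12. In the Snrpb library these 4 genes stood at 53.65, 62.34, 82.2 and 106.19 cRPKM, and in the combined library at 57.45, 79.79, 112 and 105.54 cRPKM. Sm core genes without Snrpb and Snrpd2 had a median of −0.344 with Snrpb, 0.07 with Snrpd2 and −0.23 with both. Each value rests on 1 library.

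Single genes with uneven reads among the 2-cell libraries are listed next, all of them picked from the cumulus and granulosa cell marker list. Hsd3b1 stood at 6.99 cRPKM (466 reads) with Snrpd2 and at 0.13, 0.17 and 0.08 cRPKM with mCherry, Snrpb and both (8, 10 and 5 reads). Cyp11a1, which starts steroid synthesis, stood at 3.84 against 0.26, 0.21 and 0.18 cRPKM, and Star, a cholesterol carrier, at 0.59 against 0.09, 0.29 and 0.12 cRPKM. The inhibin subunit gene Inha had 55 reads with mCherry and 2, 6 and 0 with Snrpb, Snrpd2 and both, and Inhbb had 152, 46, 19 and 8 reads. The cumulus and granulosa list did not pass for the 2-cell injections (camera, adjusted p = 0.972). Its medians were −0.118 (−0.884 to 0.303), 0.234 (−0.729 to 0.618) and 0.039 (−0.785 to 0.249) but its means −0.4, 0.041 and −0.71 with Snrpb, Snrpd2 and both.

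Some genes that rose from the 1-cell to the 2-cell stage were already higher in the injected 1-cell libraries than in the 1-cell control, and others were not. Psmd3 stood at 26.76 cRPKM in the control and at 56.86, 82.05 and 50.28 with Snrpb, Snrpd2 and both, Ddb1 at 31.57 against 60.86, 108.36 and 70.08, and Tcl1 at 573.83 against 1324.55, 1588.11 and 977.87. Cdkn1a and Snrpc, which also rose with stage, stood at 5.46 and 9.22 cRPKM in the control and at 4.15 and 6.52 with Snrpb, 3.33 and 6.14 with Snrpd2, and 5.15 and 7.34 with both. Trp53, which fell with stage, stood at 56.92 against 50.12, 49.81 and 46.04 cRPKM.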
